A study of Mus musculus with 6 samples.

How the data were processed

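Gene expression had been measured on Affymetrix arrays in cultures of mouse bone marrow mesenchymal stem cells seeded densely or sparsely and collected on 3 days, 1 array per density and day. Per the labels' protocols, cells were grown in a commercial stem cell medium, total RNA was extracted with TRI reagent and biotin-labelled cRNA was hybridised. The log2 values used here are those deposited by the authors, 1 per probe set and array; the submitters' processing notes name RMA and Partek without versions. Background correction, the array model and the annotation release are not given in the sources used here. RMA log2 values compress differences near background, so that folds of dim genes are understated. The authors' deposited table also gives, for all 35556 probe sets, a p-value and a signed linear fold change of dense against sparse, per the file headers. Recomputed here, that p-value is the one of an unpaired equal-variance comparison of the 3 dense with the 3 sparse arrays without the day (largest gap 0.00216 on the p scale), and that fold is the difference of the group means (largest gap 7.69e-05 on the log2 scale). A further 6 columns of per-sample values in that table were not used here.

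Gene symbols came from the authors' deposited table, which names 25917 probe sets and leaves 9639 without a symbol. Of 22349 distinct symbols, 19017 are current in the RefSeq gene table of assembly GRCm38.p6, 2421 matched only as a synonym and 911 did not match; the deposited symbols were kept and no coordinates were used. For each of the 1954 symbols with more than 1 probe set, the probe set with the highest mean over the 6 arrays was taken. Genes with a mean log2 value at or above the 25th percentile of all named genes (3.32) were tested, which left 16762. Values were used as deposited: array medians ran from 4.33 to 4.45, and 75th percentiles from 6.82 to 6.86 in dense and 6.66 to 6.75 in sparse arrays. The number of arrays limits the precision.

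The density and the day of each array came from the labels. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, defaults, 2-sided p, Benjamini-Hochberg adjustment, adjusted p under 0.05, no minimum fold). Dense against sparse was fitted as density plus the day as a factor (2 residual degrees of freedom), the day trend as density plus the day as a number (3) and the interaction as the difference of slopes per day (2). Single days have 1 array per density, so that log2 differences and the number of genes at least 2-fold apart are given without a test. The day pairs a dense with a sparse array by the labels; the deviations of same-day arrays from their density means correlated at 0.127, 0.0750 and 0.0674 across genes, and those of arrays of different days at −0.150 to 0.109, so that the same-day values do not stand apart from them; the day was kept as the labelled design factor.

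Before the data were examined, 37 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists covered cell cycle, matrix, differentiation, signalling, stress and metabolism, and markers of macrophages, granulocytes, lymphocytes, erythroid cells and megakaryocytes, endothelium and osteoclasts. They were tested with camera (preset correlation 0.01) against all other tested genes, adjusted over the 37 lists, with camera under an estimated correlation and fry as alternatives. Fry's directional p asks whether a list's genes move one way on balance, without comparing them with other genes; its mixed p, which asks whether they move in any direction, was not used for calls. Named genes are the 15 largest differences in each direction among genes past the test with the same sign on all 3 days, the 8 steepest slopes in each direction among genes past the test (for the day trend, where none passed, among the 200 with the smallest p), the 3 largest differences in each direction on each day, and up to 4 members of each list with the largest estimate. Some genes that this rule picks are not reported here.

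The steps were tested on simulated data: 16762 genes were given their observed means and variances drawn from the distribution limma had fitted, and 200 genes were changed, 50 at each fold. For dense against sparse, 4% of genes changed 1.5-fold, 44% of those changed 2-fold, 96% at 4-fold and 100% at 8-fold were recovered, and 4.69% of calls were false. For the day trend, with folds per day, the shares were 68%, 96%, 100% and 100% with 7.61% false calls, and for the interaction 0%, 66%, 100% and 100% with 3.62% false. Here and for the lists, genes were simulated as independent of each other and without shifts between arrays. The shares of false calls need not hold for the data. With no list moved, camera called 0 of 37 lists for dense against sparse. With the complement list moved by 0.5 on the log2 scale camera called that list (adjusted p = 1.88e-10). The estimated correlation (adjusted p = 0.867) and fry (adjusted p = 0.433) did not. In the data the estimated correlation within a list reached 0.987, for G2 phase and mitosis between dense and sparse. The simulation therefore cannot show how often camera calls such lists falsely.

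Alternatives were no filter, a filter at the 50th percentile, quantile normalization again, centring each array on its median, an intensity trend in the variance, other thresholds, the mean of a gene's probe sets, every probe set on its own (26667 tested), the day left out or as a number, and leaving out arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.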

Results

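Mesenchymal stem cells, the adherent stromal cells of bone marrow that can form bone, fat and cartilage, had been taken from mouse marrow and grown at 2 seeding densities. Dense cultures received 167 times as many cells as sparse cultures, which received 15000. RNA was taken 1, 2 and 3 days after seeding and 1 Affymetrix array was read per density and day, which gave 6 arrays, 3 per density. The labels call the cell samples independent and give no further replication. The titles of all 6 arrays share a prefix whose meaning is not given. With 1 array per density and day, p-values do not measure the spread of replicate cultures. Those of dense against sparse rest on how much the density difference varied between days. Those of the slope difference rest on departures from a straight line over the days. Each array gave log2 values for 35556 probe sets, with array medians from 4.33 to 4.45. The design asks how the expression profiles of dense and sparse cultures differ over 3 consecutive days. On the principal components of the tested genes, component 1 held 63.8% of the variance and separated the densities, with scores of −12.0, −37.7 and −47.0 for dense days 1 to 3 and 36.2, 33.1 and 27.4 for sparse days 1 to 3. Component 2, with 15.6% of the variance, ran from 24.7 on dense day 1 to −27.9 on dense day 3, while the sparse arrays lay between −4.45 and −3.89.

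**Figure D1:**
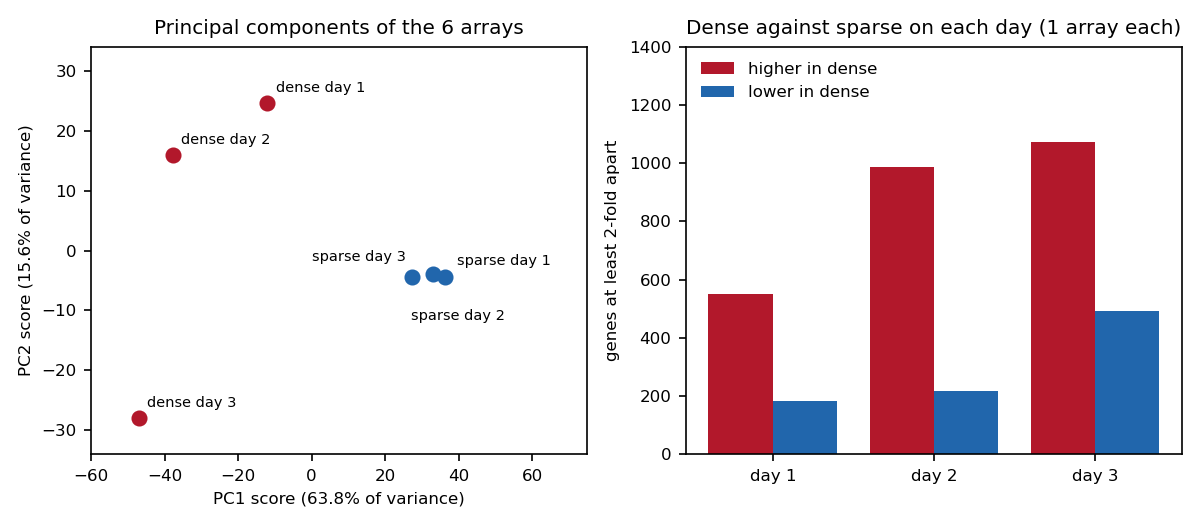
Left, scores of the 6 arrays on the leading principal components of the log2 values of the tested genes. Right, number of genes at least 2-fold higher (red) or lower (blue) in the dense than in the sparse array of each day: 551 and 181 on day 1, 988 and 216 on day 2, and 1073 and 493 on day 3.

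The largest single differences between dense and sparse cultures included genes of secreted proteins, enzymes and matrix receptors. The neutrophil-attracting chemokine Cxcl5 (probe set 10523120) was highest, with a log2 difference of 5.78 ± 0.21 (SE, 3 arrays per density) and a limma adjusted p of 0.00354. The metalloreductase Steap4 was 39.1-fold higher, and Dio3, which inactivates thyroid hormone, 21.1-fold higher. The complement protease C1s was 19.4-fold and the acute phase protein haptoglobin, Hp, 11.7-fold higher. The sparse values of Steap4 (4.16 to 4.26) and Dio3 (3.92 to 4.32) lay under the array medians. So did those of C1s (4.04 and 3.99) and Cxcl5 (4.29 and 4.04) on days 2 and 3, so that the sizes of these differences are uncertain. Matrix-related genes among the largest increases were the collagen-binding integrin Itga11 (13.5-fold) and the proteoglycan Ogn (11.5-fold).

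Secreted signalling proteins were also among these genes. Pappa2, a protease that cleaves IGF-binding proteins, was 16.9-fold higher by the brightest of its 3 probe sets. Further ones were the Wnt antagonist Sfrp1 (12.6-fold), Bmp4 (9.07-fold) and the chemokine Cxcl3 (8.89-fold, with a probe set that can read near-identical relatives). Others were the cell surface peptidase Mme (11.9-fold), Tmem45a (9.01-fold) and the potassium channel Kcnj2, whose fold is not given because its sparse values of 2.78 to 3.44 lay near the filter floor of 3.32. Their adjusted p-values ran from 0.00354 for Cxcl5 to 0.0189 for Mme. Each was higher in dense on 3 of 3 days, which the naming rule required. The sparse day 3 value of Pappa2, 3.76, and the sparse day 2 value of Hp, 3.71, also lay near the filter floor. Their folds are therefore uncertain.

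In the other direction, the gelatinase Mmp9 was 8.31-fold lower in dense cultures (log2 difference −3.05 ± 0.63, adjusted p = 0.0390). The difference was −4.54 on day 1 and −1.04 on day 3. Without the day 1 arrays Mmp9 had −2.31 and did not pass (adjusted p = 0.0673), nor did it with every probe set tested on its own (adjusted p = 0.0796). The orphan receptor Gpr149 was 8.20-fold lower by the brighter of its 2 probe sets (log2 difference −3.04, against −1.69 with their mean), and the guanine nucleotide exchange factor Dock8 7.88-fold lower. Histone genes Hist1h2ab (6.06-fold) and Hist1h2bb (3.61-fold), whose probe sets can read near-identical copies, were lower as well. Adhesion molecules on this side were the laminin-binding integrin Itga6 (5.37-fold), the semaphorin Sema7a (4.37-fold) and Alcam (3.60-fold). The plasminogen activator inhibitor Serpinb2 was 5.64-fold lower, the acyl-CoA synthetase Acsbg1 4.62-fold. The dense day 3 values of Gpr149, 3.56, and Serpinb2, 3.85, lay near the filter floor too, so that their folds are uncertain. Lce1h (3.89-fold), the ubiquitin hydrolase Uchl1 (3.73-fold) and the cardiac troponin Tnnt2 (3.71-fold) were also among the largest decreases. Uridine phosphorylase, Upp1, had dense values of 3.35 to 3.75, and the prolactin relative Prl2c5, which has close gene copies, 3.51 and 3.86 on days 3 and 2, near the filter floor, so that their folds are not given. All of these genes were lower in dense on 3 of 3 days, which the naming rule required. With every probe set tested on its own Upp1 (adjusted p = 0.0614) and Lce1h (adjusted p = 0.0562) did not pass, and without the day as a block Serpinb2 did not (adjusted p = 0.0616).

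**Figure D2:**
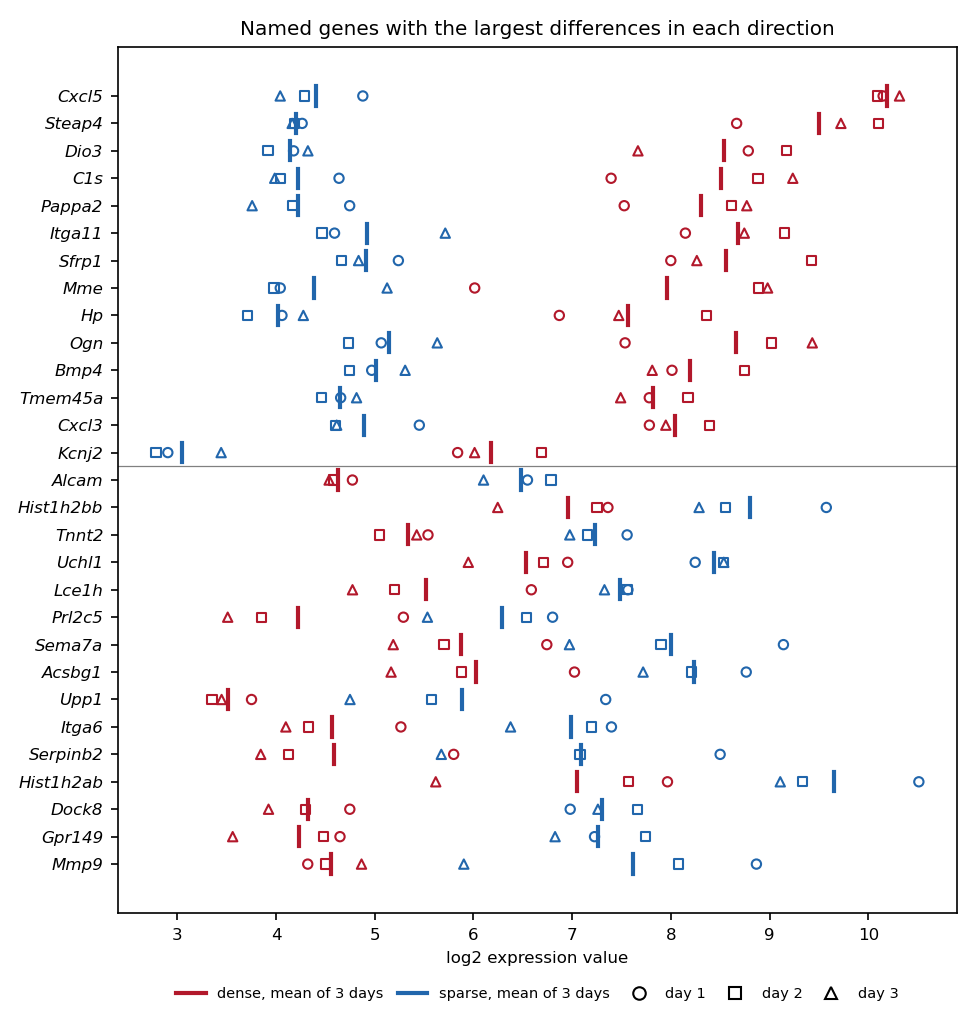
Log2 expression values (horizontal axis) of named genes with the largest differences in each direction, with 1 symbol per array (circle day 1, square day 2, triangle day 3), red for dense and blue for sparse, and bars at the mean of the 3 days. The dense values of Cxcl5 lie from 10.1 to 10.3 and its sparse values from 4.04 to 4.88.

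Of 37 gene lists, 10 were higher and 4 lower in dense cultures by camera with a preset correlation of 0.01. As many lists were called in 4 of the 10 ways to split the 6 arrays into 3 and 3, the real one included. The other splits also carry part of the density effect, and the number of list calls alone does not set the densities apart. Collagens and other structural matrix genes were higher for 15 of 27 measured members (20 adjusted over the list alone, 1 of them lower), led by Ogn (3.52), Col3a1 (2.86), Col12a1 (2.84) and Col6a1 (2.33), with adjusted p = 1.33e-07 and adjusted p = 0.678 with an estimated correlation. Matrix proteases and their inhibitors had 9 of 18 members higher and 1 lower (11 and 3 adjusted over the list alone). Among them were Serpinb2 at −2.49, Mmp19 at 2.41, Adamts5 at 2.26 and Mmp13 at 1.96 without passing (list adjusted p = 0.00164, and adjusted p = 0.678 with an estimated correlation). Complement and acute phase genes were higher for 8 of 12 members (9 adjusted over the list alone), among them Serping1 (3.07), an inhibitor of complement proteases, with adjusted p = 3.33e-05 and adjusted p = 0.678 with an estimated correlation. Interferon response genes passed for 5 of 23 members (14 adjusted over the list alone), with Ifit1 at 1.88, Gbp2 at 1.35, Irf9 at 0.95 and Ifi44 at 1.83 without passing (adjusted p = 6.39e-05, and adjusted p = 0.678 with an estimated correlation).

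Genes of low oxygen response and glycolysis were higher for 12 of 26 members (16 adjusted over the list alone), led by the mitophagy receptor Bnip3 (2.53), the pyruvate dehydrogenase kinase Pdk1 (2.33), Ddit4 (1.88) and Ero1l (1.84), with adjusted p = 1.33e-07 and adjusted p = 0.678 with an estimated correlation. CDK inhibitors and quiescence genes were higher for 10 of 18 members (11 adjusted over the list alone), including Gas1 (2.88), Txnip (2.82), Sepp1 (2.06) and Cdkn2b (1.90), the gene of a CDK inhibitor (adjusted p = 2.18e-05, and adjusted p = 0.678 with an estimated correlation). Lysosome and autophagy genes were higher for 8 of 22 members (13 adjusted over the list alone), with Ctsb at 0.97, Lamp2 at 0.97 and Grn at 0.88 (adjusted p = 7.98e-06, and adjusted p = 0.678 with an estimated correlation). Unfolded protein and amino acid stress genes passed for 3 of 21 members (9 adjusted over the list alone), with Vldlr at 2.88 and Herpud1 at 1.21, while Trib3 at 1.63 and Ddit3 at 1.57 did not pass (adjusted p = 1.30e-04, and adjusted p = 0.678 with an estimated correlation).

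Wnt pathway genes were higher for 7 of 25 members (9 adjusted over the list alone, with 1 more lower). The leading ones, Sfrp1 (3.65), Sfrp2 (3.10), Wisp2 (2.58) and Dkk3 (1.91), encode secreted proteins, of which the Sfrp family binds Wnt ligands and opposes their signal. The list had adjusted p = 0.0145, and adjusted p = 0.678 with an estimated correlation. Cholesterol synthesis genes had a median difference of 0.51 (adjusted p = 0.00261, and adjusted p = 0.678 with an estimated correlation), but 0 of 24 members passed limma's test on their own or adjusted over the list alone. The largest of them were Hmgcs1 (1.46), Tm7sf2 (1.18), Cyp51 (1.15) and Stard4 (1.05). Without the day 1 arrays the adjusted p of this list was 0.0669 and without the day 2 arrays 0.110.

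Lower in dense cultures were 4 lists. Replication-dependent histones were lower for 11 of 14 members (14 adjusted over the list alone), with Hist1h2ab at −2.60, Hist1h2bb at −1.85, Hist1h2bm at −1.57 and Hist1h1a at −1.54 (adjusted p = 8.18e-09, and adjusted p = 0.678 with an estimated correlation). DNA replication and S phase genes passed for 4 of 30 members (11 adjusted over the list alone), with the chromatin assembly subunit Chaf1b at −1.27 and cyclin gene Ccne1 at −0.85, while Rrm2 at −1.41 and Mcm5 at −1.01 did not pass (adjusted p = 6.27e-07, and adjusted p = 0.678 with an estimated correlation). Ribosome biogenesis genes were lower for 5 of 22 members (5 adjusted over the list alone), led by Rrp12 (−1.08), Bop1 (−1.02), Utp20 (−0.82) and Polr1b (−0.81), with adjusted p = 0.00164 and adjusted p = 0.678 with an estimated correlation. Genes of G2 phase and mitosis had a median of −0.50 (adjusted p = 0.00335, and adjusted p = 0.678 with an estimated correlation) with 0 of 30 members past limma's test, over all genes or adjusted over the list alone. Their largest differences were Anln (−1.03), Plk1 (−0.98), Mki67 (−0.86) and Birc5 (−0.85). Without the day 3 arrays the median of this list was 0.11 (adjusted p = 0.719).

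**Figure D3:**
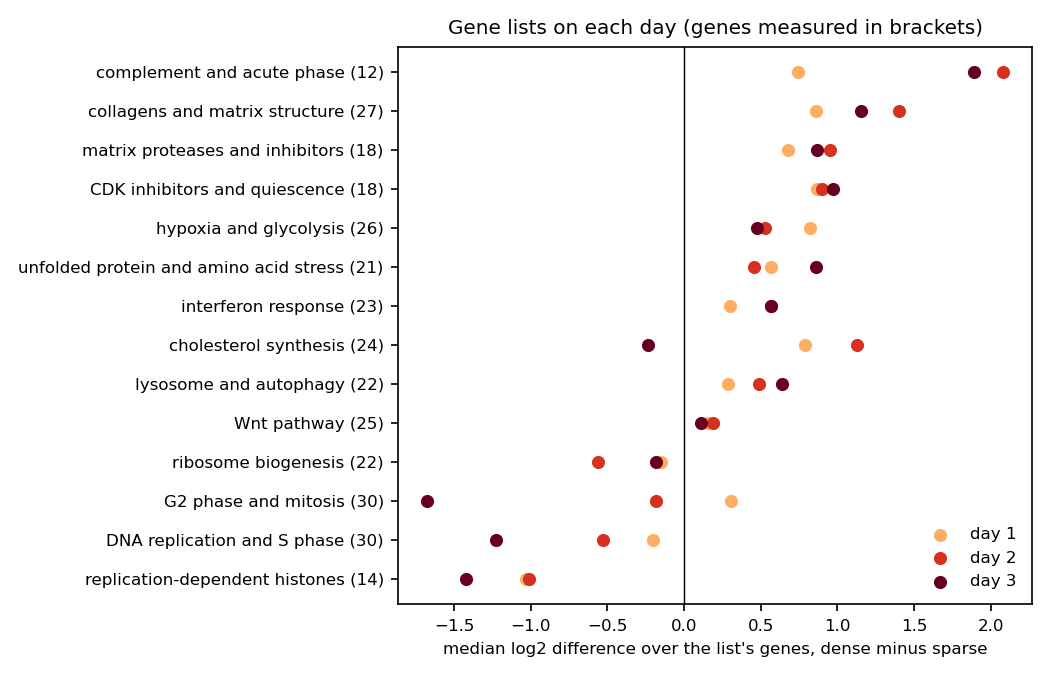
Median log2 difference, dense minus sparse, over the measured genes of each list past the camera test, with 1 point per day. Complement and acute phase genes lie at 0.75, 2.08 and 1.89 on days 1 to 3, and genes of G2 phase and mitosis at 0.31, −0.18 and −1.68.

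Lineage lists did not pass as sets, although single members did. Of 17 osteoblast genes, 6 were higher in dense (6 adjusted over the list alone, with 2 more lower), among them Bmp4 (3.18), alkaline phosphatase Alpl (2.89) and the bone transcription factor Sp7 (1.67), with Ibsp at 1.32 not passing (list adjusted p = 0.151). Of 22 adipocyte genes, 5 were higher and 2 lower (6 and 3 adjusted over the list alone), with the regulators Cebpd (1.92) and Cebpb (1.33), the fatty acid carrier Fabp4 (1.24) and Scd1 (1.23) leading (adjusted p = 0.448). Of 13 chondrocyte genes only Col11a1 (1.41) passed, over all genes or adjusted over the list alone (adjusted p = 0.151), and Sox9 had −0.46. Among 19 surface and niche markers of mesenchymal stem cells, 7 were higher and 2 lower (7 and 4 adjusted over the list alone), with Ly6a at 2.48, Pdgfra at 1.81, Lepr at 1.60 and Alcam at −1.85 (adjusted p = 0.177). Pluripotency genes passed for 0 of 12 members in limma's fit, also adjusted over the list alone, with Nanog at 0.48 and Pou5f1 at −0.44 (adjusted p = 0.247).

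Inflammatory mediators under NF-kB had 5 of 22 members higher and 1 lower (8 and 3 adjusted over the list alone), with Cxcl5 past the test and Lcn2 (3.47), Saa3 (3.46) and Ccl5 (2.17) not (list adjusted p = 0.151). YAP and TAZ target genes moved both ways, 5 higher and 2 lower of 22 (5 and 4 adjusted over the list alone), with F3 at 2.32, Tgfb2 at 1.47, Nuak2 at −1.24 and Gadd45a at 1.39 without passing (adjusted p = 0.686). TGF-beta and BMP pathway genes had 6 of 24 higher and 1 lower (8 and 1 adjusted over the list alone), with Tgfbi at 2.97 and Pmepa1 at −1.44 (adjusted p = 0.177). Smooth muscle actin cytoskeleton genes had Itga1 (2.32) as the single one of 20 that passed, also adjusted over the list alone (adjusted p = 0.799). Cell-cell adhesion genes had 4 higher and 1 lower of 26 (8 and 4 adjusted over the list alone), with Cdh3 at 1.26 and Ncam1 at 1.01 (adjusted p = 0.730), a median of −0.07 and a camera direction upward.

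Further lists that did not pass were p53 targets (3 of 19 higher; 3 higher and 1 lower adjusted over the list alone; adjusted p = 0.448), led by Trp53inp1 at 1.92, and the imprinted growth network (2 of 16 higher and 1 lower, the same adjusted over the list alone; adjusted p = 0.576), with Mest at −0.99. MHC class I presentation genes had 3 of 18 higher (5 adjusted over the list alone; adjusted p = 0.151), led by H2-T23 at 1.10. Immediate early genes, which respond to handling within minutes, had 4 of 19 higher and 1 lower (8 and 2 adjusted over the list alone; adjusted p = 0.172), with Egr1 at 1.39. In limma's fit 0 of 14 Notch pathway genes passed (adjusted p = 0.214) and 0 of 25 oxidative phosphorylation genes (adjusted p = 0.883), also adjusted over each list alone. Cytoplasmic ribosomal proteins had 1 of 26 higher, Rpl22 at 0.76 (1 adjusted over the list alone; adjusted p = 0.730).

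Markers of other marrow cell types did not pass as sets. The 13 measured macrophage and leukocyte markers had a median difference of −0.09 and 0 passed in limma's fit (adjusted p = 0.576), with a median level of 3.78 on the log2 scale. Granulocyte markers had Mmp9 lower as 1 of 7 (adjusted p = 0.229), lymphocyte markers 0 of 8 (adjusted p = 0.315), endothelial markers 0 of 12 (adjusted p = 0.151) and erythroid and megakaryocyte markers 1 of 9 higher, Ppbp at 0.93 (adjusted p = 0.576), with the same counts adjusted over each list alone. Osteoclast markers had Mmp9 lower as 1 of 6, with Ctsk at 1.46 higher only when adjusted over the list alone (adjusted p = 0.576).

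In the limma fit of density with the day as a block, 1384 of 16762 genes were higher and 486 lower in dense cultures at an adjusted p under 0.05, and 586 and 122 of these were at least 2-fold apart. All 1870 had the same sign on 3 of 3 days. The fit's residual is the spread of the daily differences, so that genes with a change of sign could hardly pass. An unadjusted p under 0.05 was found for 5748 genes, where 838 would be expected. With an estimated correlation camera called 0 of 37 lists (2 at an unadjusted p under 0.05), and fry called 0 (15 at an unadjusted p under 0.05). In the simulation both also missed a list that had been moved, so that these 0 calls do not show unmoved lists. Without both day 2 arrays limma called 0 genes (2531 at an unadjusted p under 0.05; smallest adjusted p = 0.0803), and without both day 3 arrays 1717 higher and 805 lower. Quantile normalization applied again gave 1085 higher and 816 lower genes, so that the higher share was 57.1% against 74.0% with the values as deposited. In the authors' deposited table, whose p-values match an unpaired test without the day, 7247 probe sets had p under 0.05, 3723 higher and 3524 lower in dense, and 931 of them were at least 2-fold apart. After Benjamini-Hochberg adjustment of those p-values 18 probe sets passed 0.05. Of the 1870 genes called here, 1681 (89.9%) had an unadjusted p under 0.05 in the authors' deposited table, as had 4603 of the 16762 tested. Both tests used the same arrays, so that this overlap is not separate support.

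On single days, with 1 array per density and no test, Cxcl5 was among the 3 highest genes in dense on each day, and Mmp9 was lowest on days 1 and 2. On day 1 Cxcl5 (5.27), Dio3 (4.61) and Steap4 (4.40) were highest and Mmp9 (−4.54), the small nucleolar RNA Snora44 (−4.19) and Upp1, with a dense value near the floor, lowest in dense relative to sparse. On day 2 Steap4 (5.91), Cxcl5 (5.80) and Dio3 (5.25) led, with Mmp9 (−3.58), Dock8 (−3.37) and Gpr149 (−3.26) at the other end. On day 3 Cxcl5 (6.27), the iron-carrier binding protein Lcn2 (5.96) and the bone and muscle peptide gene Ostn led, the last without a size because its sparse value of 2.74 lay under the filter floor, with the keratin Krt19 (−3.59), Hist1h2ab (−3.49) and Dock8 (−3.34) lowest. Lcn2 had a difference of 0.00 on day 1 and 4.44 on day 2.

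Genes at least 2-fold apart numbered 732 on day 1, 1204 on day 2 and 1566 on day 3. Of the 16762 genes, 252 were at least 2-fold higher and 57 at least 2-fold lower in dense on every day, and 9746 (58.1%) had the same sign on all 3 days, where unrelated days would give 25%. Across genes, which are not independent replicates, the daily differences correlated at r = 0.718 between days 1 and 2, 0.740 between days 2 and 3 and 0.461 between days 1 and 3, pairs of days that share no array.

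The slope per day common to both densities asks which genes moved with time in culture. Of 16762 genes 0 passed limma's test (smallest adjusted p = 0.128), with 970 positive and 1581 negative slopes at an unadjusted p under 0.05, and 0 passed with limma's intensity-trended variance. None of the genes named here for time passed the test. The steepest negative slopes were Serpinb2 (−1.19 ± 0.15 SE per day, adjusted p = 0.151), Prr11 (−0.94), Hist1h2ab (−0.94), Sema7a (−0.93), the basophil protease Mcpt8 (−0.91), the mitotic kinesin Kif14 (−0.81), the ERK phosphatase Dusp5 (−0.80) and cyclin F, Ccnf (−0.78). Positive slopes were those of Pck2 (0.82), Mir143 (0.69), Gpnmb (0.68), the serine synthesis enzyme Psph (0.68), Gdf15 (0.63), the amino acid transporter Slc1a4 (0.61), the integrin Itga1 (0.55) and the protease inhibitor Timp3 (0.52), with adjusted p-values from 0.151 to 0.202 over the 16 genes. Without the dense day 3 array 3 genes passed: Serpinb2 (adjusted p = 0.00696), Sema7a (adjusted p = 0.0247) and the matrix protease Adamts5 (0.99 per day, adjusted p = 0.0415), the last named after its value was seen.

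As sets, cell cycle genes fell over the days by camera, in the average of both densities: G2 phase and mitosis with a median slope of −0.61 (adjusted p = 1.93e-14, and adjusted p = 0.605 with an estimated correlation). DNA replication genes fell with −0.39 (adjusted p = 2.06e-12, and adjusted p = 0.605 with an estimated correlation) and histones with −0.31 (adjusted p = 5.33e-09, and adjusted p = 0.605 with an estimated correlation). Inflammatory mediators under NF-kB fell with a median slope of −0.17 (adjusted p = 0.00164, and adjusted p = 0.605 with an estimated correlation) and ribosome biogenesis genes with −0.10 (adjusted p = 0.0450, and adjusted p = 0.747 with an estimated correlation). Collagens rose with 0.18 (adjusted p = 8.17e-06, and adjusted p = 0.605 with an estimated correlation). Lysosome genes rose with 0.16 (adjusted p = 1.52e-05, and adjusted p = 0.605 with an estimated correlation) and stress genes of unfolded protein and amino acids with 0.25 (adjusted p = 1.54e-05, and adjusted p = 0.605 with an estimated correlation). Wnt pathway (0.08, adjusted p = 0.0204), interferon (0.13, adjusted p = 0.0288) and complement genes (0.17, adjusted p = 0.0456) rose too, each with adjusted p = 0.605 with an estimated correlation. With an estimated correlation camera called 0 of 37 lists for the slope (0 at an unadjusted p under 0.05), and fry called 0 (6 at an unadjusted p under 0.05). After quantile normalization again the interferon and complement lists no longer passed (adjusted p = 0.0907 each), nor did ribosome biogenesis (adjusted p = 0.172). The median slopes were not alike at the 2 densities: NF-kB mediators had 0.01 in dense and −0.28 in sparse, interferon genes 0.21 and 0.02, complement genes 0.34 and 0.04 and lysosome genes 0.22 and 0.05, while those of collagens were 0.17 and 0.21 and of the Wnt pathway 0.09 and 0.09. DNA replication genes had −0.67 in dense and −0.09 in sparse, histones −0.45 and −0.20, stress genes 0.36 and 0.17, and ribosome biogenesis genes −0.11 and −0.07. Over all genes 0 members of these lists passed limma's test. Adjusted over the list alone 21 mitotic, 13 histone, 6 DNA replication and 5 NF-kB genes had negative slopes. Positive ones were 5 stress genes, 4 collagens, 1 Wnt pathway gene and 1 lysosome gene, and 0 members of the interferon, complement and ribosome biogenesis lists passed either way.

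Within each density, where 1 array per day allows no test, the dense cultures had 850 genes at least 2-fold apart between days 1 and 3 and the sparse cultures 358. From day 2 to day 3 the numbers were 460 in dense, 174 higher and 286 lower on day 3, and 46 in sparse. Across genes, the slopes of dense and sparse cultures correlated at r = 0.0996.

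The difference between the slopes asks whether density changed the course over the days, and 13 genes had a higher and 19 a lower slope in dense cultures. Among them Mcam, an adhesion molecule of stromal and endothelial cells, had slopes per day of −0.89 in dense and 1.40 in sparse (difference −2.28 ± 0.17 SE, adjusted p = 0.0146). The growth factor binding matrix protein gene Ctgf had slopes of −1.29 in dense and 0.52 in sparse (difference −1.81, adjusted p = 0.0231), and the keratin Krt19 of −1.33 and 1.22 (difference −2.55, adjusted p = 0.0380). Rrm2, the ribonucleotide reductase subunit needed for DNA synthesis, had −1.38 in dense and 0.06 in sparse (difference −1.43, adjusted p = 0.0483). Lower slopes in dense were also found for Snord116 (−2.54, a small nucleolar RNA cluster with 24 probe sets), Galntl4 (−1.84), Mir680-1 (−1.77) and the LIM domain gene Fhl1 (−1.38). The sparse day 1 values of Snord116, 2.77, and Mir680-1, 3.20, lay under the filter floor, so that their slope differences are uncertain.

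Higher slopes in dense were led by Rgs16 (1.99), a regulator of G protein signalling that went from 9.81 to 6.37 in sparse cultures, and Igfbp4 (1.97), which binds insulin-like growth factors. The cysteine synthesis enzyme gene Cth (1.81) went from 7.40 to 10.8 in dense, and the thioredoxin inhibitor gene Txnip (1.77) from 8.87 to 10.8. Bone sialoprotein, Ibsp (1.57), went from 3.25 to 6.28 in dense, against 3.32 and 3.22 in sparse. Except for 6.28 these values lay near or under the filter floor of 3.32, so that its slope difference is uncertain. Odz4 (1.85), Phyhd1 (1.75) and the interferon-induced gene Ifi44 (1.38) likewise were more than 2-fold higher on day 3 than on day 1 in dense cultures only. The sparse values of Ifi44, 3.36 to 3.72, and of Odz4, 3.78 to 4.03, lay near the filter floor, so that their slope differences are uncertain too. Adjusted p-values of these 8 genes ran from 0.0146 to 0.0483. Of the 16 genes named for their slopes, only Mcam, Ctgf, Rgs16, Igfbp4 and Odz4 passed without a filter on low values, and these except Odz4 with the stricter filter. The others had adjusted p-values from 0.0511 (Krt19) to 0.0585 (Rrm2) without a filter.

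**Figure D4:**
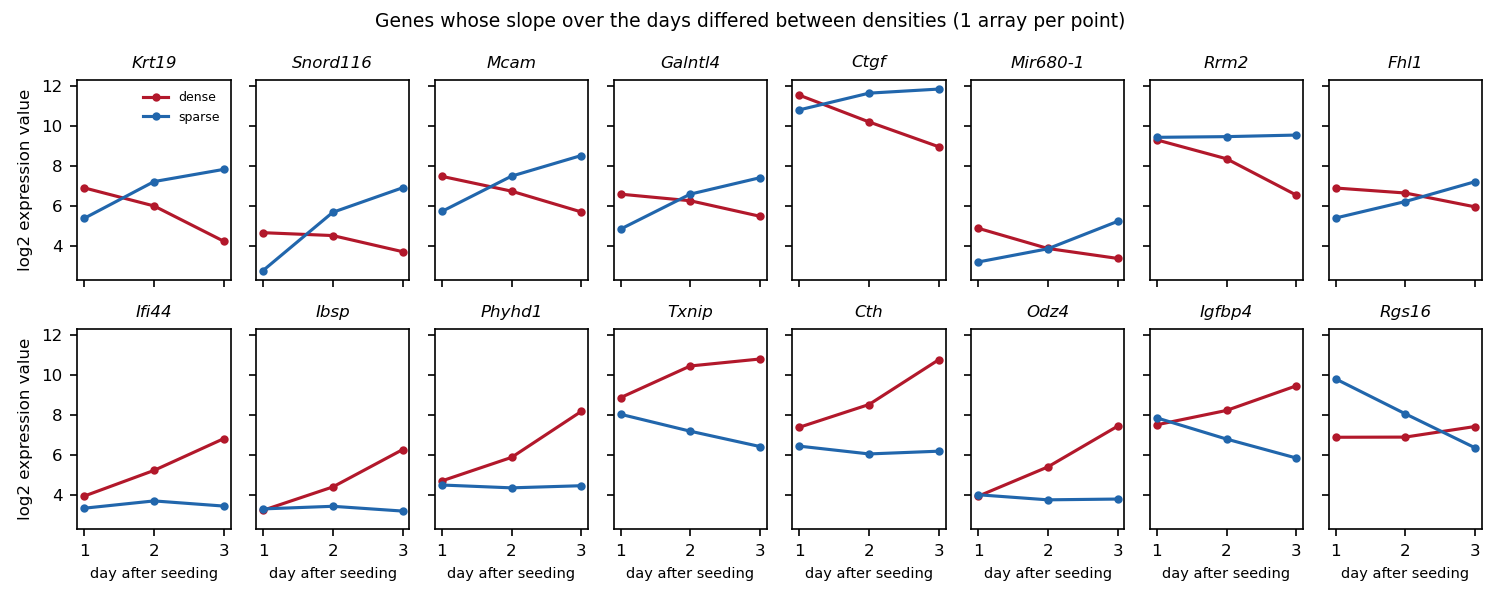
Log2 expression values by day after seeding of the 16 named genes whose slope differed between dense (red) and sparse (blue) cultures, 1 array per point. Krt19 goes from 6.90 to 4.23 in dense and from 5.38 to 7.82 in sparse.

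G2 phase and mitosis genes had a median slope of −1.12 per day in dense and −0.13 in sparse, a median difference of −1.003 (adjusted p = 2.13e-31, and adjusted p = 0.757 with an estimated correlation). Over all genes 1 of 30 members passed, and 30 adjusted over the list alone. The largest differences, none past the test over all genes, were those of Ccnb2 (−1.48), Mki67 (−1.27), Nuf2 (−1.24) and Cenpf (−1.21). From day 1 to day 3 all 30 had a lower value in dense and 25 in sparse, and their median difference between the densities went from 0.31 on day 1 to −1.68 on day 3. DNA replication genes had a median slope difference of −0.56, with 1 of 30 passing, Rrm2, and 25 adjusted over the list alone (adjusted p = 7.11e-18, and adjusted p = 0.757 with an estimated correlation). Histone genes had −0.32, with 0 of 14 passing over all genes or adjusted over the list alone (adjusted p = 0.00233, and adjusted p = 0.793 with an estimated correlation).

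**Figure D5:**
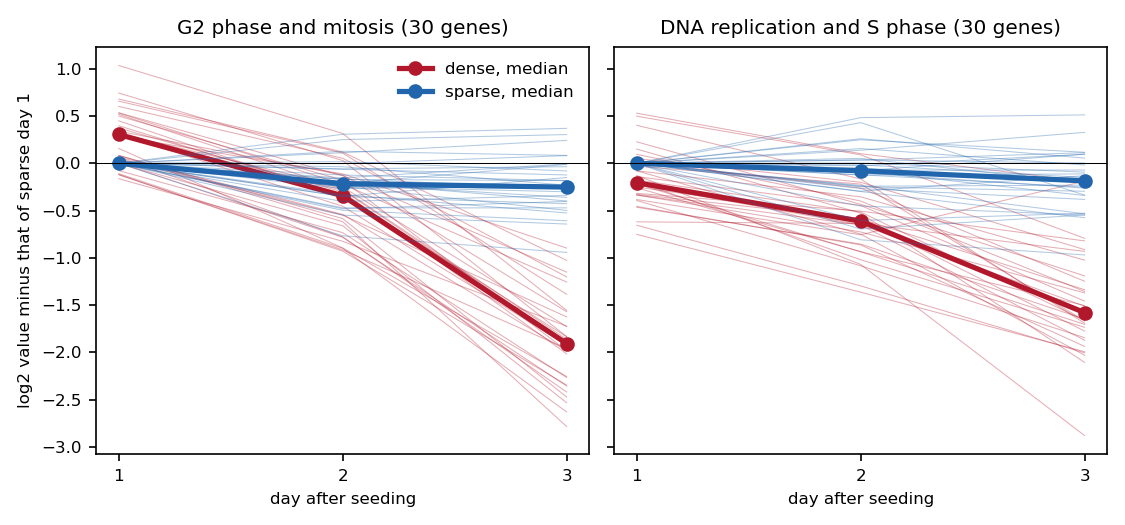
Log2 values minus the value on sparse day 1, by day after seeding, for 30 genes of G2 phase and mitosis (left) and 30 of DNA replication (right), thin lines for genes and thick lines for medians, red dense and blue sparse. All 30 mitotic genes are lower in dense than in sparse on day 3.

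Contractile and metabolic lists also had lower slopes in dense. Smooth muscle actin cytoskeleton genes had a median difference of −0.47 (1 of 20 passing, the calponin gene Cnn1 at −1.11, and 12 adjusted over the list alone; adjusted p = 6.14e-11, and adjusted p = 0.757 with an estimated correlation). Cholesterol synthesis genes had −0.63 (0 of 24 in limma's fit, also adjusted over the list alone; adjusted p = 6.58e-05, and adjusted p = 0.793 with an estimated correlation), going from a median of 0.79 higher in dense on day 1 to −0.24 on day 3. TGF-beta and BMP pathway genes had −0.22 (2 of 24 passing, Id2 among them, and 8 lower and 1 higher adjusted over the list alone; adjusted p = 1.30e-04, and adjusted p = 0.757 with an estimated correlation). Oxidative phosphorylation had −0.21, with 0 of 25 passing and 1 lower adjusted over the list alone (adjusted p = 1.92e-04, and adjusted p = 0.757 with an estimated correlation). Hypoxia and glycolysis genes had −0.20, with 0 of 26 passing, and 2 higher and 5 lower adjusted over the list alone (adjusted p = 0.00233, and adjusted p = 0.757 with an estimated correlation). Upward were complement genes at 0.43 (adjusted p = 0.00309, and adjusted p = 0.793 with an estimated correlation) and lysosome genes at 0.18 (adjusted p = 0.00608, and adjusted p = 0.757 with an estimated correlation). NF-kB mediators had 0.13 (adjusted p = 0.0126, and adjusted p = 0.757 with an estimated correlation), and so had interferon genes (adjusted p = 0.0351, and adjusted p = 0.757 with an estimated correlation). Over all genes 1 member of these 4 lists passed, Ifi44, while adjusted over the list alone 5 complement, 6 NF-kB, 2 interferon and 0 lysosome genes did. Without a filter the interferon list no longer passed (adjusted p = 0.0624). With an estimated correlation camera called 0 of 37 lists for this difference (1 at an unadjusted p under 0.05), and fry called 0 (6 at an unadjusted p under 0.05). With the preset correlation, 6 of the 10 splits of the arrays called as many lists, the real one included, and another called 15.

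For the difference of slopes 2713 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.0146. The count rests on few degrees of freedom: without a sparse array of any day limma called 0 genes (809, 2135 and 1391 at an unadjusted p under 0.05 without day 1, 2 or 3), and without a dense array of day 1, 2 or 3 it called 1236, 1740 and 438. Testing every probe set on its own it called 0 (3569 at an unadjusted p under 0.05).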

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

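The tests of explanations for the mitotic genes were chosen after the result was seen, while the counts over other splits of the arrays were set beforehand. A test of the difference between the slopes of dense and sparse cultures picked out 13 genes with a higher and 19 with a lower slope in dense. The named ones were, per day and dense minus sparse, Krt19 (−2.55), Snord116 (−2.54), Mcam (−2.28), Galntl4 (−1.84), Ctgf (−1.81), Mir680-1 (−1.77), Rrm2 (−1.43) and Fhl1 (−1.38) on the lower side. On the higher side were Rgs16 (1.99), Igfbp4 (1.97), Odz4 (1.85), Cth (1.81), Txnip (1.77), Phyhd1 (1.75), Ibsp (1.57) and Ifi44 (1.38). Values of Snord116, Mir680-1 and Ibsp under the filter floor make their slope differences uncertain. Those of Ifi44 and Odz4 are uncertain too, with sparse values near that floor. Of the 10 ways to split the 6 arrays into 3 and 3, 1 gave as many genes, the real one with 32, and the highest of the others gave 0. All of the others mix the densities and leave part of the density effect in the residual, so that their 0 is largely set by the design. For the lists 6 of the 10 splits gave as many calls, with 12 in the real split and 15 at most in another. With 10 splits no share can fall under 0.1.

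Among probe sets without a gene symbol, which enter no comparison of genes, 147 of 6026 tested passed the test between dense and sparse when every probe set was tested on its own. What they measure was not analysed here.

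Genes of G2 phase and mitosis fell faster over the days in dense than in sparse cultures by camera with a preset correlation, but not with an estimated one (adjusted p = 0.757) or with fry (adjusted p = 0.267), and 1 of 30 members passed over all genes. The list's median slope difference of −1.003 lies below the lowest median of random lists matched on expression, −0.33. A shift common to genes of like level is thus argued against. Camera had already set this list apart from other genes, so that the comparison is not separate support for the fall. From day 1 to day 2 the change was already more negative in dense by a median of −0.46, with 29 of 30 genes below 0. The 2.5th percentile of matched lists was −0.18. The median differences between the densities of 0.31, −0.18 and −1.68 on days 1 to 3 put most of the shift on day 3, however. The list's genes had an estimated correlation of 0.909 and each point is 1 array, so that the dense day 3 array as the main source stays open. Blood cells in the dense day 3 culture stay open: 0% of 70 blood cell markers reached the median of tested genes on that array (6.10), but levels of different probe sets cannot be compared and the markers lay near the floor. A slowing of proliferation in crowded cultures may account for the pattern and was not tested.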

How the results depend on the processing

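No test in this part was added after the data were seen; a planned comparison with the authors' fold changes on single days could not be run, because they are not split by day. For dense against sparse (1384 higher, 486 lower), an adjusted p under 0.1 gave 2530 and 1586, a 2-fold minimum 586 and 122, every probe set on its own 649 and 154, the day as a number 2184 and 1218, and quantile normalization again 1085 and 816. Leaving out both arrays of a day gave 0 to 1717 higher and 0 to 805 lower; the 0 came without day 2. The paired day is in the design by the labels, and without this block 1702 and 516 genes passed, sharing 1605 of 1870, and 14 lists as before. The day trend gave 0 genes except 3 without the dense day 3 array (range 0 to 3). The interaction (13 higher, 19 lower slopes) gave 3 and 2 without a filter, 2 and 2 with the stricter one, 32 and 52 with an intensity trend, 214 and 221 at an adjusted p under 0.1, 0 and 0 with every probe set on its own, and 0 to 915 and 0 to 825 without 1 array. Leaving out 1 array fits that density's line exactly, so that the spread comes from the other density alone; the cause of the other shifts was not tested. Quantile normalization kept 30 and centring 31 of its 32 genes.

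With an estimated correlation and with fry, camera's 14, 11 and 12 list calls became 0 and 0 in each comparison. Both had missed a moved list in the simulation, so that the lost calls cannot tell false calls from a lack of power. The list of G2 phase and mitosis changed sign between dense and sparse without day 3, to a median of 0.11 (range over the 3 days left out −0.91 to 0.11). A 1.5-fold limit gave 2766, 3557 and 3882 genes on days 1, 2 and 3. Of 906 values of named genes under the alternatives 786 kept direction and side of the threshold, 118 lost the call, 2 gained it and 0 changed sign. For dense against sparse 383 kept both and 35 lost the call, and for the interaction 152 kept both and 83 lost it. The remaining 251 kept values and the 2 gains were of day trend genes, which had no call to lose. Of 241 values of called lists 159 kept both and 81 lost the call. Signal over background was not analysed here, so genes near the filter are the least certain.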

Other observations

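In this part the tests on complement and interferon genes and on the higher share among all called genes were chosen after the result was seen. Between day 2 and day 3, compared on single arrays without a test, the 21 genes of the list of unfolded protein and amino acid stress had a median change of 0.62 in dense cultures, with 15 higher on day 3, and 0.19 in sparse cultures, with 16 higher. The largest changes in dense were those of the cystine transporter gene Slc7a11 (2.55), Trib3 (2.40), Ddit3 (2.37) and Atf3 (2.22), against 0.37, 0.55, 0.09 and 0.36 in sparse. No explanation of these values was tested.

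The sparse cultures may have moved toward the dense state as they grew. Across genes, which are not independent replicates, the sparse change from day 2 to day 3 correlated with the dense minus sparse difference of day 1, with which it shares no array, at r = 0.271 (Spearman's rho 0.213). The dense change from day 2 to day 3 gave r = −0.168. The test had been set before its result was seen; time in culture at any density remains open as an explanation.

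Complement, acute phase and interferon genes were higher in dense cultures, by a median of 0.58 over 35 genes, of which 8 of 12 complement and 5 of 23 interferon genes passed. The list calls were lost with an estimated correlation (adjusted p = 0.678 each) and with fry (adjusted p = 0.0916 and 0.111). The highest median of matched random lists was 0.30, so that a shift common to genes of like level is argued against. Camera had already set these lists apart from other genes, so that this comparison is not separate support for the difference. Blood cells carried into the dense cultures stay open: macrophage and leukocyte markers had a median difference of −0.0867, the largest being 0.50 for H2-Ab1, but they lay near the floor. Of 9 erythroid and megakaryocyte markers, also near the floor, 3 were higher and 6 lower in dense, with a median of −0.19. Among these the platelet gene Ppbp passed at 0.93. An inflammatory state of the stromal cells at high density may account for the pattern and was not tested apart from density.

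More called genes were higher than lower in dense cultures, 74.0% of all calls. An unequal distribution of values left by the authors' normalization cannot be told apart from a true excess for all calls, since the share was 57.1% after quantile normalization again, between the bounds set for either reading. For calls at least 2-fold apart the share was 75.4% after it, 480 higher and 157 lower, against 82.8% as deposited, which argues against that explanation there. Of the 10 splits of the arrays 1 called as many genes between the groups, the real one with 1870, and the highest other called 0. Only 3 of the other 9 part all 3 days as the real one does, and they also called 0. The rest estimate the group effect from 1 day. All 9 leave part of the density effect in the residual, so that their 0 is largely set by the design. For the lists 4 of 10 splits called as many, 14 in the real and 14 at most in another. Splits this few cannot give a share under 0.1.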
